A study of Mus musculus with 6 samples.

How the data were processed

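RNA from Mvt-1 cells, a mouse mammary tumour line derived from mice carrying Myc and Vegf transgenes, was measured on 6 single-colour Illumina expression beadchips, 3 of vehicle-treated and 3 of insulin-treated cells. Per the labels' protocols, the cells had been starved of serum for 16 h and then received insulin at 10 nM for 90 min, and total RNA was amplified and labelled with biotin before hybridization. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

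The deposited table of non-normalized values held, per the file headers, a signal for each of 45281 probes on each array, which is an intensity on a linear scale without background subtraction. Beside each signal stood the detection p-value of that probe on that array, per the file headers. Per the submitters' processing notes the values came from GenomeStudio, with the version and settings not given in the sources used here. The authors' deposited processed values were also linear intensity values, and a quantile normalization of the 6 columns of non-normalized signals gave each of them to within 3.33e-06. Their column medians were 76.6 or 76.7 on every array, and they carried no background correction, no centring and no log scale. All per-sample columns were matched to a sample by name. Slide and scan date were not used here.

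Signals were background-corrected with limma's neqc, which fits a normal-exponential model to background estimated from the detection p-values, with an offset of 16, followed by quantile normalization and log2. This correction stretches differences among dim probes relative to bright ones. A probe was kept when its detection p was under 0.05 on at least 3 of the 6 arrays, which left 17482 probes. Gene symbols came from the platform annotation supplied with the series. Of all probes, 34885 had 1 gene symbol, 18 had several and 10378 had none there, and a probe without a symbol is unnamed here, not without a gene. The Entrez identifiers of 34807 probes matched the RefSeq gene table of GRCm38.p6, which changed 0 symbols. No coordinates are given, because the genome build behind the probe design is not given in the sources used here. Of the detected probes, 15007 had a single gene and 2475 did not and were left out of the gene-level test. For each gene the probe with the highest mean over the 6 arrays was used, giving 9478 genes, of which 3746 had more than 1 detected probe.

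Insulin was compared with vehicle by limma (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05, without the replicate number in the model. A probe that was not detected on any array of a group had only a bound there. Its fold was computed against, per array, the higher of the lowest detected signal and the probe's own value, and is written as "at least". The genes named in the text followed a rule set before the data were examined, as were the groups, tests, alternatives and gene lists. The rule took the 10 largest rises and 10 largest falls past the threshold whose 3 insulin arrays all lay on the same side of all 3 vehicle arrays, skipping symbols without a known gene. It also took, from each list, up to 4 members past the threshold or, where there were none, the member with the smallest p, and in addition Insr, Igf1r, Irs1, Irs2, Myc and Vegfa. Other genes named were chosen after their values were seen.

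The 16 gene lists covered immediate-early transcription factors, MAP kinase feedback regulators, FOXO targets, insulin receptor signalling components, SREBP targets, glycolysis, ATF4 targets, MYC targets with ribosome biogenesis, G1 to S phase genes, mitosis genes, growth factors with cytokines and secreted proteases, NF-kB targets, epithelial and mesenchymal markers, markers of other cell types, heat shock with the unfolded protein response, and hypoxia targets. Each list was tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 16 lists. Camera with an estimated correlation and the rotation test fry were alternatives. Camera compares a list with all other genes, whereas fry asks whether the members move, on balance, one way.

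The whole procedure was tested on simulated data in 3 runs of 9931 genes with 200 changed genes each, for the comparison of insulin with vehicle. Changed genes were counted only where they passed the filter with the changed probe in use. Of these the procedure recovered 20.6% of 136 changed by 0.5 on the log2 scale and 67.2% of 137 at 0.75. It recovered 82.1% of 140 at 1 and 90.6% of 138 at 1.5, with 0 calls in the wrong direction and 7.67% false calls. Each run held more changed genes than the 44 called in the data, which makes the adjusted threshold easier to reach. The list of MYC targets and ribosome biogenesis, shifted by 0.2 in the simulation, was called in 3 of 3 runs, and 0 other lists were called. The changed genes were drawn from outside all lists, so the other lists were given no change and that 0 was nearly fixed in advance. Every member of the shifted list was shifted equally and noise was drawn separately for each gene, so these runs set no limit for real lists. The number of arrays limits the precision of every value.

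Alternatives covered the background correction, the normalization between arrays, the authors' deposited processed values, the filter on dim probes, the treatment of several probes per gene, the variance model, array weights, a replicate block, a minimum fold of 1.5, the set test, and leaving out each of the 6 arrays in turn. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with matplotlib 3.10.9 for the figures.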

Results

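Transcript levels were measured in serum-starved Mvt-1 mouse mammary tumour cells after 90 min with 10 nM insulin or vehicle, on 3 arrays per group. Each array carried 45281 probes, and 17617 to 18232 of them, or 38.9% to 40.3%, were detected per array. Median signals lay between 76.0 and 77.1, against a range of signals from 62.5 to 13285.1, so much of the array sat near background. Over the 9478 genes tested, after normalization and log2, the lowest correlation between any pair of arrays was r = 0.988 and the highest 0.992. At most 0.757% of probes had the same signal on a pair of arrays, so no array was counted as a duplicate. The leading principal component took 31.0% of the variance and placed the vehicle arrays at -11.1, -3.19 and -11.2 and the insulin arrays at 8.97, 14.5 and 2.03.

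The comparison of insulin with vehicle addressed which transcripts change early after insulin reaches breast tumour cells, in a study concerned with the insulin receptor. Fbxo32, a muscle-atrophy ubiquitin ligase subunit, fell 2.44-fold, a log2 change of -1.29 ± 0.15 (standard error, n = 3 per group, limma with Benjamini-Hochberg, adjusted p = 0.00109), the largest change past the threshold with the neqc correction and the brightest probe per gene. That rank was lost with normexp fitted to the signals (Fbxo32 -0.74, Tnfrsf12a 0.88). With the authors' deposited processed values it was lost too, where Fbxo32 changed by -0.64 and Ets2 by 0.80. It was also lost with the mean of each gene's probes, where Fbxo32 changed by -0.75 and Zkscan14 by -1.06. Ccng2, the cyclin G2 gene expressed in cells leaving the cycle, fell 1.93-fold (log2 change -0.95 ± 0.13). Txnip, which restrains glucose uptake, fell 1.76-fold (log2 change -0.81 ± 0.14). Tnfrsf12a, the receptor for the cytokine TWEAK, rose 1.99-fold (log2 change 0.99 ± 0.20), and Ets2, a transcription factor downstream of MAP kinase, rose 1.81-fold (log2 change 0.86 ± 0.14).

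In all, 44 of 9478 genes passed the threshold, 12 higher and 32 lower with insulin, so that 72.7% of the calls were lower, and 43 of them had a fold of at least 1.5. With the authors' deposited processed values, which carry no background correction, 11 genes were higher and 11 lower, and 19 of the 44 calls were kept. Called changes ranged from 0.58 to 1.29 in size on the log2 scale, against a median standard error of 0.13. In all 44 called genes the 3 insulin arrays lay on one side of the 3 vehicle arrays. The calling rule favours such genes, so this is no separate check of the calls. Over all genes tested, 1510 were separated in this way, or 15.9% against the 10% that chance gives. At an unadjusted p under 0.05 there were 1038 genes, 455 higher and 583 lower, where chance would give 473.9. Of the called genes, 13 had a further detected probe, and 19 of 19 such probes moved the same way, 9 of them with an unadjusted p under 0.05. Without 1 array the counts of higher and lower genes were 3 and 9 (without vehicle replicate 1), 1 and 5 (vehicle replicate 2), 0 and 3 (vehicle replicate 3), 3 and 8 (insulin replicate 1), 2 and 8 (insulin replicate 2), and 37 and 32 (insulin replicate 3). Fbxo32 and Zkscan14 passed without any 1 of the 6 arrays, and without the filter on dim probes 0 genes passed, Fbxo32 reaching an adjusted p of 0.0953 (limma; over all alternatives from 6.12e-06 to 0.0953).

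**Figure D1:**
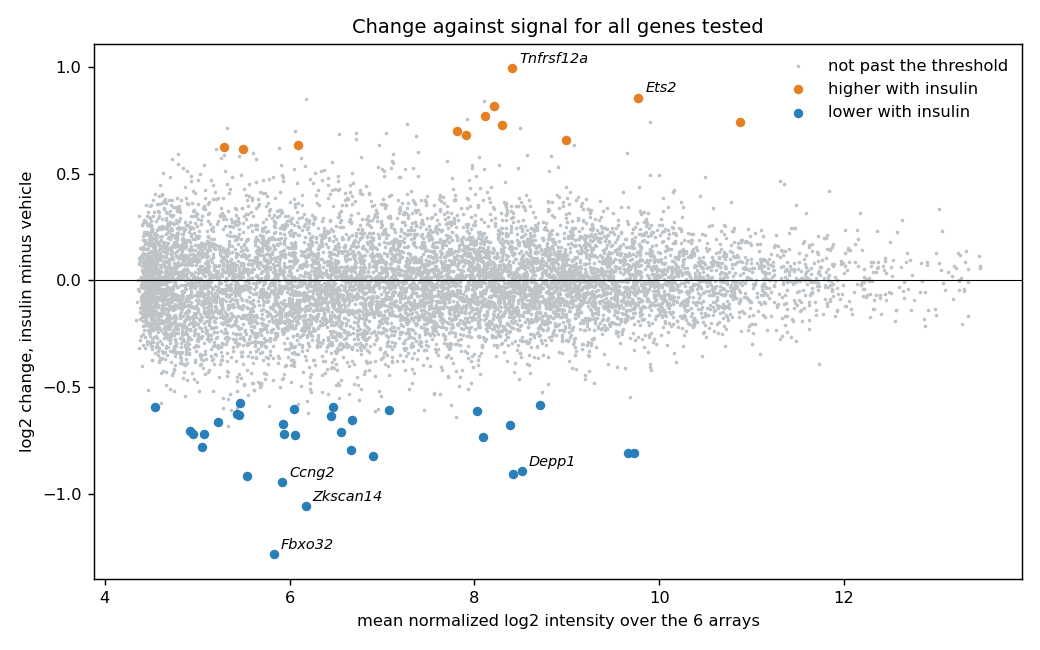
Each point is 1 of the 9478 genes tested, with its mean normalized log2 intensity over the 6 arrays across and its log2 change, insulin minus vehicle, upward, coloured where the adjusted p was under 0.05. The 32 lower calls had a median intensity of 6.12 and the 12 higher calls one of 8.16, against 7.28 for all genes.

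Among the 10 largest falls, Zkscan14, a zinc finger gene, followed Fbxo32 with a log2 change of -1.06 ± 0.14 (limma, Benjamini-Hochberg adjusted p = 0.0058). Ankrd37, an ankyrin repeat gene induced by hypoxia, fell by 0.92 on the log2 scale, and Depp1, a FOXO-regulated gene linked to autophagy, fell by 0.90, with the same adjusted p of 0.0058. Ccn2, a matricellular protein also called CTGF, changed by -0.91 ± 0.16 and a further probe for it by -1.01. Klf2, a Krüppel-like transcription factor, changed by -0.82 ± 0.14, Hbp1, a repressor of cell cycle genes, by -0.81 ± 0.14, and Zc3h6, a zinc finger gene, by -0.79 ± 0.16. A further probe for Txnip changed by -1.07, those for Hbp1 by -0.49, -0.58 and -0.21, and those for Fbxo32 by -0.77 and -0.20. With the mean of each gene's probes Hbp1 changed by -0.52 and lost its call (limma adjusted p = 0.10), as did Zc3h6 (adjusted p = 0.0619). Without background correction the changes of dim genes were smaller, at -0.64 for Fbxo32, -0.58 for Zkscan14, -0.48 for Ccng2, -0.51 for Zc3h6 and -0.41 for Ankrd37, and the calls of Zc3h6 and Ankrd37 were lost. Leaving out vehicle replicate 3 ended the calls of Ccng2 and Depp1 (both limma adjusted p = 0.0659), and leaving out vehicle replicate 2 ended that of Ankrd37 (adjusted p = 0.0506), while Ccn2, Klf2, Txnip, Hbp1 and Zc3h6 each passed without at most 3 of the 6 arrays in turn.

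Among the 10 largest rises after Tnfrsf12a and Ets2, Trmt61a, the catalytic subunit of a transfer RNA methyltransferase, rose 1.76-fold with a log2 change of 0.82 ± 0.13 (limma, Benjamini-Hochberg adjusted p = 0.0117). Pprc1, a coactivator related to PGC-1 that promotes mitochondrial gene expression, rose by 0.77 ± 0.14 on the log2 scale. H1f2, a linker histone, rose by 0.74 ± 0.14, and Arf2, a small GTPase of vesicle traffic, by 0.73 ± 0.13. Coq10b, a coenzyme Q binding protein of mitochondria, rose by 0.70 ± 0.14, Map1b, a microtubule-associated protein, by 0.68 ± 0.14, Ccdc86, a nucleolar protein, by 0.66 ± 0.13, and Dot1l, a histone methyltransferase, by 0.63 ± 0.13. Further probes gave 0.65 for Coq10b and 0.53 for H1f2, but 0.32, 0.33 and 0.11 for Map1b. With the mean of each gene's probes the calls of Map1b (0.36), H1f2 (0.64, limma adjusted p = 0.0750) and Tnfrsf12a (adjusted p = 0.0835) were lost. Without background correction Dot1l changed by 0.34 and Tnfrsf12a by 0.85, and both calls were lost. Tnfrsf12a also lost its call with a trended, robust variance model (limma adjusted p = 0.234, over all alternatives from 0.00618 to 0.307), and Ccdc86 did with median scaling. Trmt61a lost its call without vehicle replicate 3 (limma adjusted p = 0.104), and each of the other 9 passed without at most 2 of the 6 arrays in turn.

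**Figure D2:**
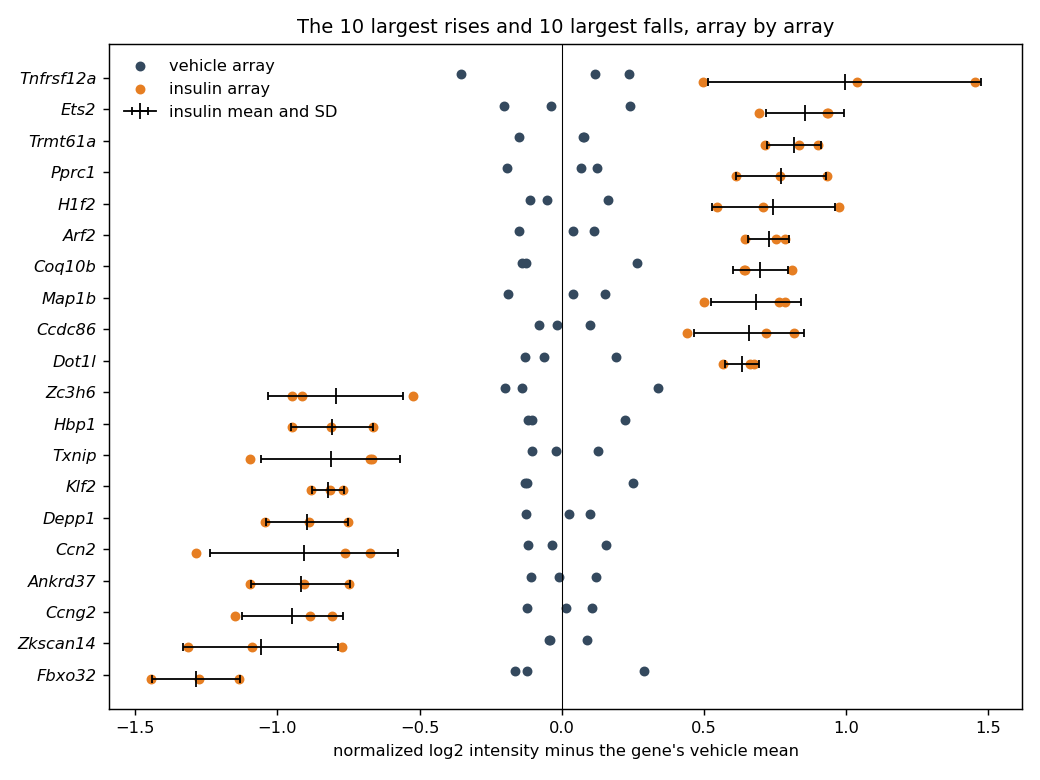
For each of the 10 largest rises and 10 largest falls, points give the 3 vehicle and 3 insulin arrays as normalized log2 intensity minus the gene's vehicle mean, and black bars the insulin mean and SD. Fbxo32 had an insulin SD of 0.16 around a change of -1.29, and Tnfrsf12a an SD of 0.48 around 0.99.

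Targets of FOXO transcription factors, which insulin signalling through AKT keeps out of the nucleus, fell as a group. Of 16 members tested, 4 fell (Fbxo32, Ccng2, Txnip and Irs2), 0 rose and 12 did not pass the threshold, 7 were lower when adjusted over the list alone, and 13 had a negative change. The list's median log2 change was -0.26 (SD over members 0.38), with a camera adjusted p of 3.60e-09 and an adjusted p = 0.0389 with an estimated correlation, so that the call held. With the preset correlation, camera called the list in 4 of 10 splits of the arrays, the division into vehicle and insulin included. The other splits kept part of the insulin difference, but the camera adjusted p of 3.60e-09 may overstate the evidence. The 3 members that passed only when adjusted over the list alone were Pdk4, an inhibitor of pyruvate dehydrogenase, at -0.53 ± 0.13, Bcl6, a transcriptional repressor, at -0.45 ± 0.14, and Insr, the insulin receptor, at -0.40 ± 0.14. Cdkn1b, Tob1 and Trib2 had small positive changes that lay within their standard errors. Of the 16 members, 3 also stood in another list.

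Genes of ribosome biogenesis and other MYC targets were higher as a list, with a median log2 change of 0.20 (SD over members 0.23) and a camera adjusted p of 2.33e-05. The call was lost at an adjusted p = 0.0533 with an estimated correlation, and 0 members passed the threshold over all genes. Of 23 members tested, 19 had a positive change, and 4 were higher and 1 lower when adjusted over the list alone. The higher members were Rrs1, at a log2 change of 0.62 ± 0.16, Nip7, at 0.53 ± 0.13, and Ddx21, at 0.49 ± 0.12, which act in ribosome assembly, and Odc1, the rate-limiting enzyme of polyamine synthesis, at 0.47 ± 0.13. Rrs1 was dim, with a mean log2 intensity of 4.89 with vehicle and 5.51 with insulin, where the background correction stretches differences. Nip7, Ddx21 and Odc1 had means of 8.21 or more in both groups. Ddx21 passed over all genes in 4 of 19 alternatives (lowest limma adjusted p = 0.0219). The lower member was Polr1c, a subunit shared by RNA polymerases I and III, at -0.42 ± 0.13. Fry gave the list an adjusted p of 0.0301. Myc itself had a log2 change of -0.035 ± 0.16 (limma adjusted p = 0.969).

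SREBP targets, the genes of sterol and fatty acid synthesis, had a median log2 change of 0.15 (SD over members 0.15) and a camera adjusted p of 0.00575. The call was lost at an adjusted p = 0.125 with an estimated correlation. Of 20 members tested, 0 passed the threshold over all genes and 0 when adjusted over the list alone, while 16 had a positive change. Scd2, a fatty acid desaturase, had the smallest p of the list, with a log2 change of 0.38 ± 0.17 that ranged from 0.22 to 0.55 over the alternatives. Stard4, a sterol carrier, stood at 0.37 ± 0.18, Idi1, an isomerase of the sterol pathway, at 0.30 ± 0.14, and Dhcr7, an enzyme of late cholesterol synthesis, at -0.22 ± 0.14. Fry gave the list an adjusted p of 0.0344.

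**Figure D3:**
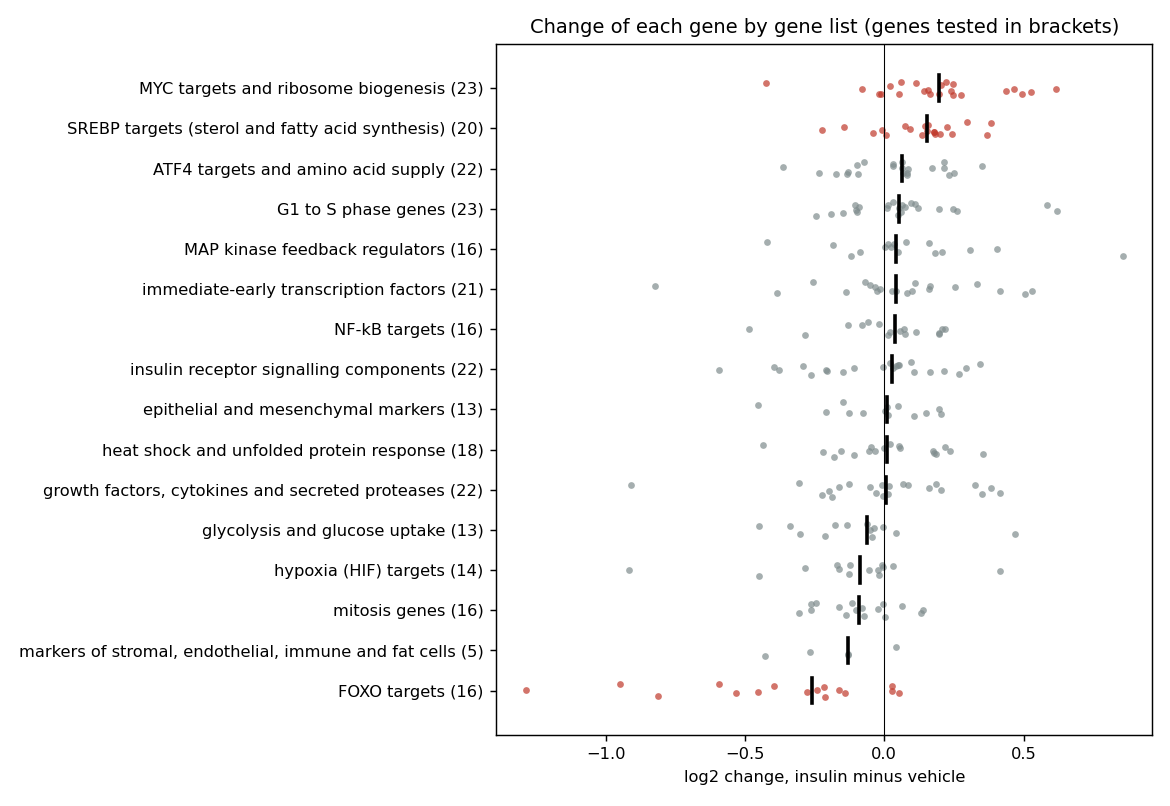
Points give the log2 change, insulin minus vehicle, of each tested gene by list, black bars the list medians, and red the 3 lists past the camera threshold. The FOXO list had the lowest median, -0.26, and the list of MYC targets and ribosome biogenesis the highest, 0.20.

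The receptor and its adaptors were looked at by name. Irs2, an adaptor of the insulin receptor, fell (limma, Benjamini-Hochberg adjusted p = 0.0454). It was detected on 3 vehicle arrays and on 0 insulin arrays, so with the neqc correction it was at least 1.30-fold lower with insulin. That bound carries no allowance for error. Irs2 changed by less than it with the authors' deposited processed values (log2 change -0.22) and with normexp fitted to the signals (-0.27). Its call was lost in 10 of 15 alternatives, among them each left-out insulin array and the authors' deposited processed values, and its adjusted p ranged from 0.0279 to 0.278. Insr had a log2 change of -0.40 ± 0.14 (adjusted p = 0.316) and Igf1r, the receptor for insulin-like growth factor, one of -0.29 ± 0.14 (adjusted p = 0.466), neither past the threshold over all genes. The change of Igf1r ranged from -0.398 to -0.035 over the alternatives. Irs1 was not detected on 3 arrays and was not tested. Of 22 insulin receptor signalling components tested, 1 fell (Irs2), 1 was lower when adjusted over the list alone, and the list was not called (camera adjusted p = 0.672). Its median of 0.026 and mean of -0.042 differed in sign, and camera's direction was down.

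The list of immediate-early transcription factors also held other genes, such as Mcl1 and Rcan1. Of its 21 tested genes, 1 fell (Klf2) and 0 rose. Adjusted over the list alone, 2 were higher and 1 lower. The 2 were Egr1 and Egr2, zinc finger factors induced by growth factors, with log2 changes of 0.53 ± 0.15 and 0.50 ± 0.13. Fos, a subunit of AP-1, stood at -0.25 ± 0.13, but it was dim, with a mean log2 intensity of 4.80 with vehicle and 4.55 with insulin. The lowest mean of any gene tested was 4.34. The list was not called (camera adjusted p = 0.271, median 0.042). In the list named MAP kinase feedback regulators, with 16 tested genes, 1 rose, Ets2, itself a transcription factor downstream of MAP kinase. Adjusted over the list alone 2 were higher, the other being Dusp2, a MAP kinase phosphatase, at 0.40 ± 0.12. Dusp2 was dim as well, with a mean of 4.41 with vehicle and 4.82 with insulin. Dusp10, a phosphatase of the same family, stood at -0.42 ± 0.15. That list was not called either (camera adjusted p = 0.157, median 0.043).

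Hypoxia targets held 14 tested genes, of which 1 fell (Ankrd37) and 12 had a negative change (median -0.088, camera adjusted p = 0.157). Adjusted over the list alone, 1 was higher and 2 were lower, namely Vegfa, the angiogenic growth factor, at 0.41 ± 0.12, against Ankrd37 and Pdk1, another inhibitor of pyruvate dehydrogenase, at -0.45 ± 0.14. Vegfa did not pass over all genes (limma adjusted p = 0.197), and whether the probes for Myc and Vegfa also read the transgenes of this line is not given in the sources used here. Of 13 glycolysis genes 11 had a negative change, with 0 called and 0 when adjusted over the list alone (median -0.062, camera adjusted p = 0.192). Pdk1, which stands in both lists, had the smallest p of the glycolysis list, and Hk1, a hexokinase, stood at 0.47 ± 0.15. Of 22 growth factors, cytokines and secreted proteases, 1 fell (Ccn2), and 1 was higher (Vegfa) and 1 lower (Ccn2) when adjusted over the list alone. Hbegf, a ligand of the EGF receptor, stood at 0.38 ± 0.14, the list's median was 0.0051 (camera adjusted p = 0.561), and camera's direction was up against a mean of -2.12e-05.

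Cell cycle genes were not called as lists. Of 23 G1 to S phase genes, 0 passed and 0 when adjusted over the list alone (median 0.055, camera adjusted p = 0.196), with Cdc25a, a phosphatase that activates cyclin-dependent kinases, at 0.62 ± 0.19 and Ccnd2, cyclin D2, at 0.58 ± 0.21. Cdc25a ranged from 0.27 to 0.85 over 19 alternatives and passed in 1 of them (limma adjusted p = 0.0269). Of 16 mitosis genes, 0 passed and 0 when adjusted over the list alone, and 12 had a negative change (median -0.089, camera adjusted p = 0.196). Bub1b, a kinase of the spindle checkpoint, had the smallest p there, with -0.31 ± 0.12.

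The remaining lists were not called. Of 22 ATF4 targets, 0 passed and 0 when adjusted over the list alone (median 0.063, camera adjusted p = 0.521), with Slc3a2, an amino acid transporter subunit, at -0.36 ± 0.16. Over the alternatives Slc3a2 ranged from -0.56 to -0.21. Of 18 heat shock and unfolded protein response genes, 0 passed and 0 when adjusted over the list alone (median 0.0098, camera adjusted p = 0.625), with Dnajb9, a chaperone of the endoplasmic reticulum, at -0.43 ± 0.14. Of 16 NF-kB targets, 0 passed and 1 was lower when adjusted over the list alone, Icam1, an adhesion molecule, at -0.49 ± 0.13 (median 0.038, camera adjusted p = 0.704). Of 13 epithelial and mesenchymal markers, 0 passed and 1 was lower when adjusted over the list alone, Snai2, a repressor of epithelial genes, at -0.45 ± 0.12. That list had a median of 0.011 and a mean of -0.022, which differed in sign (camera adjusted p = 0.847, direction down). Of 27 markers of stromal, endothelial, immune and fat cells named on the array, 5 were detected on at least 3 arrays, and of these 0 passed and 0 when adjusted over the list alone (median -0.13, camera adjusted p = 0.191), with Pdgfra, a receptor of mesenchymal cells, at -0.43 ± 0.16. The value for Pdgfra ran from -0.56 to -0.26 over the alternatives. In fry's mixed test, which asks whether genes of a list change in either direction and does not set them against other genes, 10 of the 16 lists passed.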

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

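All alternatives here were chosen before the data were examined. The called genes that were tested kept their direction in the alternatives that gave 1 value per gene. At least 1 of the counts of higher and lower calls moved by over 1.5 times in each alternative given in this paragraph. Without a filter on dim probes, limma called 0 genes higher and 0 lower among 19057 (1645 at an unadjusted p under 0.05). Testing all 17482 detected probes gave 2 higher and 8 lower. The authors' deposited processed values and no background correction, which are the same values, each gave 11 lower, and normexp with an offset of 50 gave 16 lower (55.2% of its calls). A trended, robust variance model gave 34 higher and 49 lower. Leaving out 1 array gave from 0 to 37 higher and from 3 to 32 lower, with fewer calls on fewer samples in 5 of the 6. The cause of the larger count without insulin replicate 3 (37 higher) and of the other moves was not tested. Of the 44 calls, 2 were kept in all 6 of these, 4 in 5 of 6, and 11 in none.

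In the alternatives in which lists were tested, which leave out all detected probes and the minimum fold, the 3 called lists stayed called except under camera with an estimated correlation, which left 1, the FOXO list. Some values near 0 changed sign or test direction, and the cause was not tested. Myc ranged from -0.24 to 0.10 without 1 array, the insulin signalling list's median from -0.050 to 0.020, that of NF-kB targets from -0.049 to 0.091 (0.038 with fry, whose direction was down), and that of epithelial and mesenchymal markers from -0.083 to 0.064, with 0.044 without a filter, 0.012 with detection on all 6 arrays and 0.012 at a detection p under 0.01. Over all alternatives the medians of 3 further uncalled lists crossed 0, from -0.066 to 0.036 for growth factors, -0.035 to 0.060 for heat shock and -0.0013 to 0.129 for MAP kinase feedback regulators.

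With the replicate block, 31 genes were higher and 44 lower, all 44 calls were kept and the 3 lists stayed called. Arrays sharing a number correlated, in deviations from group means over genes, at 0.0901, 0.152 and 0.131, and each array correlated best with its own number. That is a hint from the data, not the design, so the numbers were not treated as pairing the samples. A slide block was not run. Signal over background limits the sizes for dim genes.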

Other observations

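The genes and gene families of the first 2 paragraphs, the groups noticed among the calls, the tests of normalization for the lists, and the tests of background correction and dim probes were chosen after the result was seen. Several of the 32 lower genes were not taken by the rule for named genes. Bmp4, a bone morphogenetic protein, fell by 0.72 ± 0.13 on the log2 scale, Il15, a cytokine of lymphocyte survival, fell by 0.68 ± 0.13, and Cldn1, a tight junction protein, fell by 0.72 ± 0.13 (n = 3 per group, limma with Benjamini-Hochberg, adjusted p of 0.0335, 0.0390 and 0.0335). A pair of further probes for Il15 gave -0.63 and -0.99. Klhl24, a Kelch-like protein, fell by 0.74 ± 0.15, but a further probe for it gave -0.25 (limma unadjusted p = 0.0779). Nuak2, a kinase related to AMPK, fell by 0.59 ± 0.12. Each of these 5 calls was kept without at most 1 of the 6 arrays in turn, and Il15 in none.

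Gene families were also scanned without a fixed list, by grouping genes whose symbols share a stem. Of 60 such families with at least 15 genes, 0 passed camera after adjustment and 3 had an unadjusted p under 0.05. The Eif family of translation initiation factors, 40 genes, had a median log2 change of 0.07 (camera adjusted p = 0.308), the Ddx family of RNA helicases, 24 genes, one of 0.04, and the Nudt family of hydrolases, 18 genes, one of -0.12 (both camera adjusted p = 0.648).

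The fall of the FOXO list was set against signal level and normalization. Of 10000 random lists matched on mean signal, 0 had a median as far out, and over the 5 other background corrections and normalizations, 2 of which gave the same values, the highest adjusted p was 9.19e-08, which argues against both as the whole cause. The 12 uncalled members had a median of -0.21 and 9 were lower (camera p = 0.000446, and p = 0.0208 with an estimated correlation), so the fall may extend beyond the 4 called genes. What biological process lies behind the fall was not tested.

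The rises of the other 2 lists were treated in the same way. For MYC targets and ribosome biogenesis, 0 of 10000 matched lists had a median as far out, and the highest adjusted p over the normalizations was 0.00014. For SREBP targets these were 1 of 10000 and 0.0322. Neither signal level nor normalization is therefore likely to be the whole cause, but both lists lost their call with an estimated correlation (adjusted p = 0.0533 and 0.125). The estimated correlations were themselves -0.0051 and -0.015, and that form of the test takes its degrees of freedom from the arrays and not from the genes.

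That 72.7% of the calls were lower may come from the processing. Without background correction 50% were lower, from 11 higher and 11 lower calls, too few to fix the share closely. With that correction kept, the share was also 46.4% without insulin replicate 3 (72.7% to 100% without any other array), 58.7% with the replicate block and 59.0% with a trended, robust variance model, so background correction was not the only choice that moved it. There the share moved because higher calls rose from 12, to 37, 31 and 34 in that order. Lower calls did not drop, at 32, 44 and 49 against 32 in the main test. Signal level was looked at only with the correction kept, so it cannot tell the correction from a real excess of falls. Among genes with an unadjusted p under 0.05, 61.4% were lower in the dimmest of 4 equal groups by signal and 45.7% in the brightest (59 of 129). These values fit a direction set in part by dim probes and their background correction, and a real excess of falls among weakly expressed genes stays open.

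Other groups noticed among the calls gave no shift past the threshold. The lower calls held 4 genes whose symbols start with Zfp or Zkscan (Zkscan14, Zfp94, Zfp82 and Zfp119a), and the 211 tested genes of those stems gave a camera p of 0.0954. YAP and TAZ targets other than Ccn2 (15 genes) gave a camera p of 0.592. Autophagy genes (25) gave one of 0.333, and mitochondrial RNA and protein synthesis genes, looked at because Pprc1 and Coq10b rose (26 genes), one of 0.385 with a median of -0.077. The bound for these tests had been set on the p alone, and a p that misses the threshold leaves open a shift in each of these groups. The simulated shift of 0.2 sets no limit on its size. It was put equally on every member of another list, with noise drawn separately for each gene.

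The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 12 higher, 32 lower and 44 genes in all, and the highest of the other splits gave 1, 1 and 1. As large a count came from 1 of the 10 splits in each case, the real one. Every other split set a majority of vehicle arrays against a majority of insulin arrays, so part of the insulin difference stayed in it. The rest added to the spread within its groups, so these splits do not show what chance alone gives. For gene lists the real split gave 3 and the highest other 2, again 1 of 10. A list was called in 4 of the 9 other splits, and the FOXO list in 4 of 10 with the real one included. The directions of those calls were not recorded.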
